A study of Mus musculus with 6 samples.

How the data were processed

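Poly(A) RNA was sequenced from 6 libraries of thioglycollate-elicited peritoneal macrophages of female C57BL/6 mice, 1 library for each combination of 3 siRNAs (control, Smyd5, Phf2) and 2 agents (vehicle, KLA). Per the labels' protocols, RNA was fragmented, given a synthetic poly(A) tail, reverse transcribed with barcoded primers, selected by size on a gel, circularized, amplified by PCR and sequenced on a Genome Analyzer 2. No molecular identifiers are described, so reads are not independent molecules, and every counting interval given here covers counting error only. Groups were taken from the sample titles and the agent labels.

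The values used were a signal deposited by the authors, reads per RefSeq transcript scaled to 10000000 tags of the library, per the file headers, which also give the word cds, a tag total and a scaling factor for each column. HOMER and the mouse build mm9 are named, without role or version, per the submitters' processing notes. The aligner, its filters and the treatment of strand and of reads with several matches are not given in the sources used here. Coordinates are printed as the deposited table gives them, on mm9, and cover the whole transcript, while the column headers refer to coding sequence. Genes with near-identical copies, among them ribosomal protein, histone, Ifit, Oas, Mx and class II genes, are therefore uncertain where reads could be split or dropped, and overlapping or antisense genes cannot be told apart.

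Whole reads were recovered from the steps in the deposited signal: each value was divided by 10000000 over a header total and called whole within 0.02 of a whole number. Both siSmyd5 columns gave 100% whole values with their own totals. The siCtl columns gave 2.43% whole values with their own totals, for vehicle and for KLA alike, and 100% with the total printed for the siPhf2 library of the same agent. The siPhf2 columns gave 1.13% (vehicle) and 0.76% (KLA) with their own totals and 100% with those printed for siCtl. The header totals of 4 columns thus disagree with their values, and either the names or the totals of siCtl and siPhf2 were exchanged when the table was written. The values were kept under the names printed on the columns, and the exchange was run as an alternative. Recovered reads do not depend on which is right, because each column has only 1 total that gives whole reads.

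The table held 29619 transcripts of 23282 symbols, and 2 transcripts without a symbol, with at most 2 reads in any library, were left out. Each symbol was represented by the transcript with the highest mean over the 6 libraries. Reads counted this way were 1359283 (siCtl vehicle), 1429520 (siCtl KLA), 921923 (siSmyd5 vehicle), 919329 (siSmyd5 KLA), 577055 (siPhf2 vehicle) and 420141 (siPhf2 KLA). Genes with a mean of at least 10 reads, 7995 in all, were tested.

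Before the data were examined, the tests, the gene lists, the rule for named genes and the other processing choices to be tried were fixed. Averaged effects came from an additive fit of siRNA and agent with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM scaling, 2-sided, Benjamini-Hochberg threshold 0.05). The fit has 2 residual degrees of freedom, and its residual holds library noise together with any difference between the KLA responses of the siRNA arms. Nothing in the labels says whether the libraries came from separate animals or cultures, so p-values measure only the spread between these libraries. The deposited unit is a scaled signal, not counts; the count model was used because the plan named it wherever whole reads could be recovered. The plan's form for scaled values, limma 3.58.1 on log2 of TMM-scaled CPM (reads scaled to a fixed library total) with their lower quartile above 0 (15.4) added, was run as an alternative, as were limma-voom and DESeq2 1.42.0.

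Contrasts of 1 library against 1 have no replicate check and carry no p-value. Their log2 ratios used TMM-scaled values with 2 reads added, and a gene was called higher or lower by size when the log2 ratio was at least 1 in either direction, the mean was at least 10 reads and the exact conditional Poisson 95% interval of the ratio excluded equality. Printed ratios and their intervals have no reads added. Where one side had 0 reads, a bound was computed against a floor of 3 reads per library. For each of 23 gene lists the median log2 ratio was compared with 10000 random lists of the same size matched on mean expression in 20 bins (1000 for alternatives), and its percentile among them describes these libraries. Genes called KLA-induced, at a log2 ratio of at least 2, were taken from the siRNA arm outside the contrast. Correlations between contrasts that share a control library were set beside 100 simulations of unchanged groups. The genes named are the 10 with the largest rise and fall of each averaged effect, of each contrast and of the genes called under both agents, those called in all 4 knockdown contrasts, Smyd5, Phf2 and members of the lists, with Irg1, Sc4mol and Jhdm1d as the table's names for Acod1, Msmo1 and Kdm7a.

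The fits were tested on simulated counts drawn from these libraries' means and sizes, with 200 genes changed for each averaged effect and 192 for each contrast. The averaged KLA fit recovered 59.5% of 2-fold and 96% of 4-fold changes, the siSmyd5 fit 66.5% and 95.5%, and the siPhf2 fit 13% and 59.5%, among 7995 genes. By size, 97.4% and 99.0% of 4-fold changes were recovered for siSmyd5 (vehicle, KLA) and 88.5% and 74.0% for siPhf2, with 33, 34, 162 and 135 unchanged genes called, among 8967 genes.

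Alternatives were DESeq2's size factors, scaling to the total, no filter, a minimum mean of 50 reads, 5 times the added reads, no block for the other factor, all transcripts as separate entries, each library and each siRNA arm left out in turn, and a lower bound for induced genes. Added after the data were seen were the exchange of the siCtl and siPhf2 names, fits without the siPhf2 or the siSmyd5 libraries, fits without Rn45s, total scaling without Rn45s, other scalings of the summed histone reads, and a length correction that subtracts the median log2 ratio of genes of like transcript length in 20 bins. Counts from the averaged fits adjusted over a list alone were not named in the plan. The B cell, dendritic cell, and eosinophil and mast cell lists had 0 members above the filter, the T and NK cell list had 1, the neutrophil list 3 and the list of mesothelial cells and fibroblasts 6. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.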

Results

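Poly(A) RNA was sequenced from thioglycollate-elicited peritoneal macrophages of female C57BL/6 mice given control, Smyd5 or Phf2 siRNA and then vehicle or KLA. The labels name the agent only by this abbreviation, which commonly stands for a lipid A that acts on the receptor TLR4. KLA was given at 100 ng per ml for 4 hours, and the siRNA time was 48 hours in every library. The series held 6 libraries, 1 for each siRNA and agent, so no group has replicates. The siPhf2-labelled libraries were the shallowest, with 577055 (vehicle) and 420141 (KLA) reads, of which the ribosomal RNA precursor Rn45s took 66.7% and 71.6%, against at most 1.2% in the other 4. Without Rn45s they held 192421 and 119136 reads, against at least 910904 elsewhere. Contrasts of 1 library with 1 compare libraries, not conditions, and every interval below covers counting error only.

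Smyd5 (NM_144918, chr6:85381970-85396423), a methyltransferase of histone H4 lysine 20, had 44 and 29 reads in the siCtl-labelled vehicle and KLA libraries, 9 and 20 in the siSmyd5-labelled libraries and 3 and 0 in the siPhf2-labelled libraries. It was lower in the siSmyd5-labelled library under vehicle, at 0.329 of control (95% interval 0.141 to 0.683), and stood at 1.10 of control under KLA (0.592 to 2.02). Phf2 (NM_011078, chr13:48897119-48966254), a histone demethylase, had 113 and 120 reads in the siCtl-labelled libraries, 52 and 34 in the siSmyd5-labelled and 29 and 8 in the siPhf2-labelled libraries. Under the siPhf2 label it was higher than control under vehicle, at 2.54-fold (1.63 to 3.86), and stood at 1.08 of control under KLA (0.457 to 2.20). Scaled to the total it was instead lower than control under both agents, at 0.595 (0.381 to 0.902) and 0.223 (0.0943 to 0.455), and with Rn45s taken out of the total it stood at 1.81 (1.16 to 2.74) and 0.793 (0.335 to 1.61). In the siSmyd5-labelled libraries Phf2 stood at 0.740 of control (0.522 to 1.04) under vehicle and 0.453 (0.300 to 0.668) under KLA. In the averaged edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment neither target passed: Smyd5 under the siSmyd5 label had a log2 fold of −0.64 (adjusted p 0.384) and Phf2 under the siPhf2 label 0.90 (adjusted p 0.0980), but −1.26, which passed, when scaled to the total.

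With TMM scaling a lower target was thus seen in 1 of 4 knockdown libraries, Smyd5 under vehicle, and Phf2 was lower only when scaled to a total filled by Rn45s, which lowered most genes. The header totals of the siCtl and siPhf2 columns fit each other's values, so the arms are called by their labels throughout and no direction is drawn from a knockdown of Phf2.

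**Figure D1:**
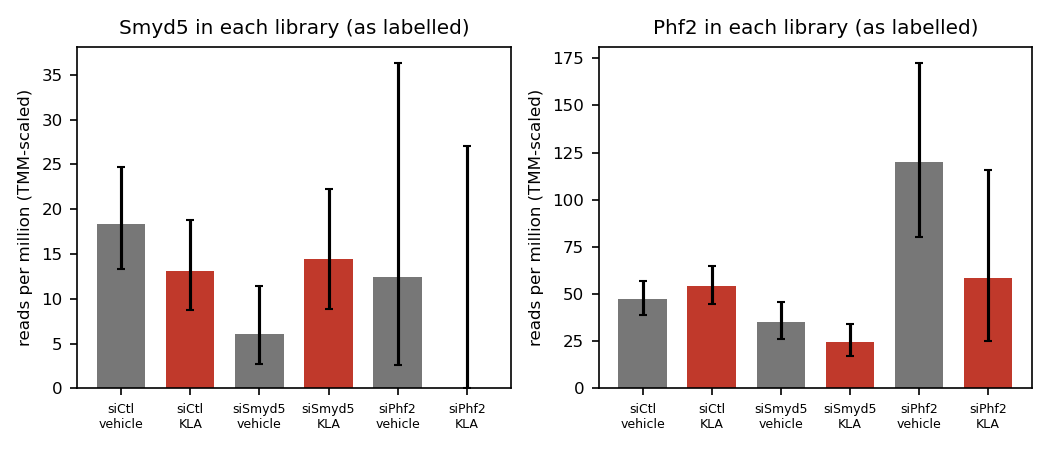
Smyd5 and Phf2 in each library, in TMM-scaled CPM with 95% counting intervals. Smyd5 ran from 0 to 18.4 and Phf2 from 24.5 to 120.

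What KLA did across the 3 siRNA arms was asked with the averaged fit, and 1256 of 7995 genes changed (891 rose, 365 fell). Inflammatory mediators rose most, among them the chemokine Cxcl10 (NM_021274, chr5:92775665-92777915; log2 fold 8.23, standard error 0.42, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p 5.45e-11), the vasoconstrictor peptide Edn1 (7.73) and the cytokines Il1b (NM_008361, chr2:129190316-129196856; 7.65) and Tnf (NM_013693, chr17:35336336-35338941; 6.77). The nitric oxide synthase Nos2 (6.73) and Irg1 (6.50), which makes itaconate, rose as well. Of the inflammatory cytokine and chemokine list 21 of 25 measured rose and 0 fell (22 and 0 adjusted over the list alone). Of the NF-kB pathway and feedback list 21 of 22 rose and 0 fell (21 and 0 alone), with the inhibitors Nfkbie (5.49) and Nfkbia (4.12) and the adaptor Traf1 (4.49) among them. Of the interferon-stimulated genes 33 of 36 rose and 0 fell (34 and 0 alone), including the GTPase Gbp5 (7.19), Ifit1 (6.11) and the antiviral enzyme Rsad2 (5.23), while Irf7, Oas1a and Psmb9 did not pass. Of the LPS effector list 18 of 20 rose and 0 fell (18 and 0 alone).

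The immediate early list was mixed under KLA: of 17 measured 8 rose and 3 fell (9 and 3 adjusted over the list alone), with Egr1 up (log2 fold 3.08) and the AP-1 members Fos (−1.80) and Jun (−1.69) down. The largest falls were the ubiquitin ligase Fbxo32 (−3.76), Vash2 (−3.67), the receptor Gpr157 (−3.53) and the GTPase Rhov (−3.42). The adaptor Sh2d3c (−2.91), the anticoagulant receptor Thbd (−2.52) and the myeloid factor Cebpa (−2.51) also fell. Of the macrophage identity list 1 of 21 rose (Cebpb) and 3 fell (1 and 3 alone). Of the lipid handling list 1 of 20 rose and 3 fell (1 and 4 alone), with the cholesterol exporters Abca1 up (1.58) and Abcg1 down (−1.22). In the H4K20 and corepressor list 2 of 17 rose and 0 fell (2 and 0 alone), the H3K27 demethylase Kdm6b (3.24) and Jhdm1d.

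The KLA count came from edgeR and was 613 with DESeq2, 968 with limma-voom and 375 with limma on log2 values. Scaling to the total gave 635 up and 536 down. It was 505 without the siCtl vehicle library, 484 without siCtl KLA, 476 without siSmyd5 vehicle, 416 without siSmyd5 KLA, 2050 without siPhf2 vehicle and 2046 without siPhf2 KLA.

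Whether the KLA response looked alike in each arm was asked with single-library contrasts. Genes called by size were 553 higher and 192 lower in the siCtl-labelled arm, 694 and 278 in the siSmyd5-labelled arm and 668 and 557 in the siPhf2-labelled arm. Scaling to the total gave 437 and 352 in the siCtl-labelled arm and 483 and 1002 in the siPhf2-labelled arm, where it moved the median log2 ratio from −0.16 to −0.45. The siCtl- and siSmyd5-labelled arms shared 471 higher genes (48.0 expected if independent) and 91 lower genes (6.68 expected), with 0 in opposite directions and a Pearson correlation across genes of 0.843. The correlations with the siPhf2-labelled arm were 0.50 (siCtl) and 0.49 (siSmyd5).

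The interferon-stimulated list was higher after KLA in every arm, with 28, 33 and 35 of 36 members called higher and medians of 2.46, 3.09 and 4.61 in the siCtl-, siSmyd5- and siPhf2-labelled arms (4.41 in the last with genes at 0 reads set to their bound). Cytokines and chemokines had medians of 4.13, 4.35 and 3.41 (4.26, 3.98 and 2.58 with genes at 0 reads at their bound), with 19, 20 and 15 of 25 called higher. For the NF-kB list the medians were 2.98, 3.34 and 2.97 (2.79 with genes at 0 reads at their bound). The same bound put the LPS effector medians of 2.36, 2.89 and 3.49 at 3.3 in the siPhf2-labelled arm. These 4 lists lay above all random lists in each arm. Lysosomal genes were slightly lower, with medians of −0.14, −0.30 and −0.46 at percentiles 0.05, 0 and 0.57. Tnf was 190-fold (132 to 287), 175-fold (102 to 330) and 41.6-fold (29.1 to 61.8) higher with KLA in the 3 arms. The growth factor gene Csf2 had 0 reads in every vehicle library and was at least 9.37-fold higher in the siCtl-labelled and at least 12.9-fold higher in the siSmyd5-labelled KLA library. Differences between arms were not tested.

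**Figure D2:**
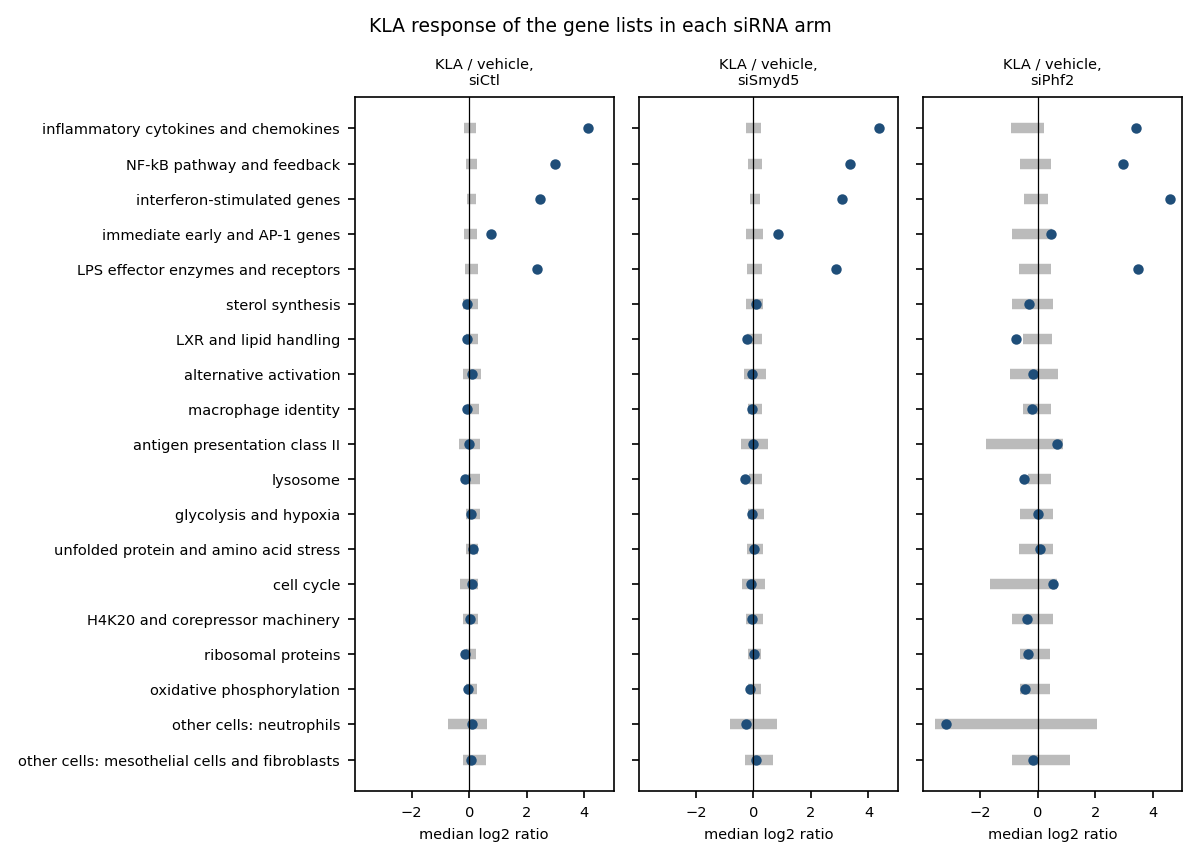
Median log2 ratio of each gene list for KLA against vehicle in the 3 arms, with the central 95% of random matched lists in grey. The interferon-stimulated list stood at 2.46, 3.09 and 4.61.

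What differed between the siSmyd5- and siCtl-labelled libraries over both agents was asked with the averaged fit, and 503 of 7995 genes changed (217 rose, 286 fell). The largest rises included the ribosomal protein genes Rps15a (log2 fold 2.49, standard error 0.30, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p 0.000502), Rpl13 (2.48) and Rpl26 (1.81). Of the ribosomal protein list 10 of 27 rose and 0 fell (19 and 1 adjusted over the list alone), and of the oxidative phosphorylation list 4 of 27 rose and 0 fell (11 and 0 alone). Sterol synthesis genes rose, 4 of 16 with 0 falling (7 and 0 alone): the methyl sterol oxidase Sc4mol (1.49), the demethylase Cyp51 (1.22), the epoxidase Sqle (1.15) and the desaturase Sc5d (1.10). The largest falls included the giant cadherin Fat1 (−2.25), the signalling adaptor Grb10 (−2.20), the transcription factor Foxo3 (−2.00) and the kinase Mast4 (−1.96).

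Of the H4K20 and corepressor list 0 of 17 rose and 2 fell in the siSmyd5-labelled libraries (0 and 4 adjusted over the list alone), Kdm6b (log2 fold −1.06) among them. Of the immediate early list 0 of 17 rose and 2 fell (0 and 3 alone), the phosphatase Dusp4 (−1.20) and Myc (−1.17). In the macrophage identity list 0 of 21 rose and 2 fell (0 and 2 alone), the lectin Siglec1 (−1.34) among them. In the lipid handling list 2 of 20 rose and 1 fell (2 and 3 alone), Abca1 (−1.04). Of 25 cytokines, 22 NF-kB genes, 36 interferon-stimulated genes and 20 LPS effectors 0 passed in either direction, within the lists alone as well.

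The siSmyd5 count depended on the method and on which libraries were in the fit, and was larger without the siPhf2-labelled ones. A fit without 1 library takes its residual only from the KLA responses of the complete arms. Without a siCtl- or siSmyd5-labelled library that includes the siPhf2-labelled arm, and without a siPhf2-labelled library it does not. Such counts therefore do not show which libraries the differences rest on. DESeq2 gave 14 genes (507 at an unadjusted p under 0.05), limma-voom 16 (1585) and limma on log2 values 0 (469), beside 1886 at an unadjusted p under 0.05 in edgeR. It was 1 without the siCtl vehicle library, 1 without siCtl KLA, 5 without siSmyd5 vehicle, 2 without siSmyd5 KLA, 2196 without siPhf2 vehicle and 2189 without siPhf2 KLA. Scaling to the total gave 59 up and 173 down.

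Whether these differences appeared under each agent was asked with the siSmyd5 single-library contrasts. By size 192 genes were higher and 401 lower in the siSmyd5-labelled vehicle library (106 and 568 with scaling to the total, which moved the median log2 ratio from −0.0050 to −0.13), and 138 were higher and 291 lower under KLA (120 and 340). Both agents shared 43 higher genes (3.3 expected if independent) and 113 lower genes (14.6 expected), with 0 in opposite directions (13.9 expected) and a Pearson correlation across genes of 0.623. Sc4mol was 2.75-fold higher (2.25 to 3.38) under vehicle and 2.89-fold (2.30 to 3.65) under KLA, and the calcium-binding S100a4 2.70-fold (1.77 to 4.17) and 2.81-fold (1.80 to 4.45). The matrix proteoglycan Hspg2 was lower, at 0.295 of control (0.207 to 0.411) under vehicle and 0.266 (0.184 to 0.374) under KLA, and the cytoskeletal linker Dst at 0.261 (0.149 to 0.432) and 0.297 (0.198 to 0.432). The sterol synthesis median was 0.55 under vehicle and 0.74 under KLA (percentiles 99.97 and 100), with 4 and 7 of 16 called higher and 0 lower, but −0.28 and 0.54 (percentiles 16.2 and 75.2) with the siCtl and siPhf2 names exchanged.

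Interferon-stimulated genes differed by agent. Their median was −0.05 under vehicle (percentile 23.5; 1 of 36 higher, 0 lower; −0.010 with genes at 0 reads at their bound) and 0.56 under KLA (percentile 100; 5 of 36 higher, 0 lower), where the antiviral GTPases Mx1 (2.39-fold, 2.16 to 2.65) and Mx2 (2.10-fold, 1.77 to 2.48) and the ISG15 protease Usp18 (2.26-fold, 1.83 to 2.80) were higher in the siSmyd5-labelled library. The NF-kB list stood at −0.32 (percentile 0.300) and 0.04 (54.0), with 0 of 22 called either way under each agent. Immediate early genes stood at −0.45 (percentile 0.410; 0 of 17 higher, 4 lower; −0.42 with genes at 0 reads at their bound) and −0.34 (0.855; 0 higher, 2 lower). Their low position was weaker with the siCtl and siPhf2 names exchanged, at −0.095 (percentile 34.85) and −0.35 (4.6). It was also weaker with a minimum mean of 50 reads, at −0.33 (4.6) and −0.35 (2.5). In the other settings tried the percentiles were at most 0.8 under vehicle and 1.6 under KLA. Egr1 was at 0.393 of control (0.183 to 0.772) under vehicle. Under KLA Tnf was at 0.687 of control (0.653 to 0.723) and Il1b at 1.41 (1.28 to 1.55), neither past the size bound. With the siCtl and siPhf2 names exchanged the interferon-stimulated median under KLA was −0.96 (percentile 0), with Mx1, Mx2 and Usp18 at log2 ratios of −1.57, −1.22 and −0.42. The difference between agents was not tested.

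The siSmyd5 log2 ratios ran with transcript length, with Spearman correlations of −0.455 under vehicle and −0.470 under KLA. The shortest 400 genes had medians of 0.59 and 0.48 and the longest −0.54 and −0.55. The siPhf2 log2 ratios ran the other way, with Spearman correlations of 0.354 and 0.252 and medians of −0.42 and −0.85 for the shortest and 0.996 and 0.375 for the longest 400 genes. The 113 genes lower under both agents had a median length of 6317 bases and the 43 higher genes 733, against 2913 for all. After the length correction the sterol synthesis medians were 0.60 and 0.78 and the interferon-stimulated median under KLA 0.53, all at percentile 100, while the oxidative phosphorylation medians were 0.12 and 0.17 (percentiles 75.6 and 92.8) with it and 0.48 and 0.43 without. The ribosomal protein medians were 0.12 and 0.28 with it (percentiles 78.0 and 99.8) and 0.70 and 0.74 without. The H4K20 and corepressor median under vehicle was −0.25 with it (percentile 3.50) and −0.44 without (0.355). For Phf2 the siSmyd5 log2 ratios under vehicle and KLA were −0.17 and −0.84 with it and −0.42 and −1.09 without. The averaged fits were not corrected for length.

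**Figure D3:**
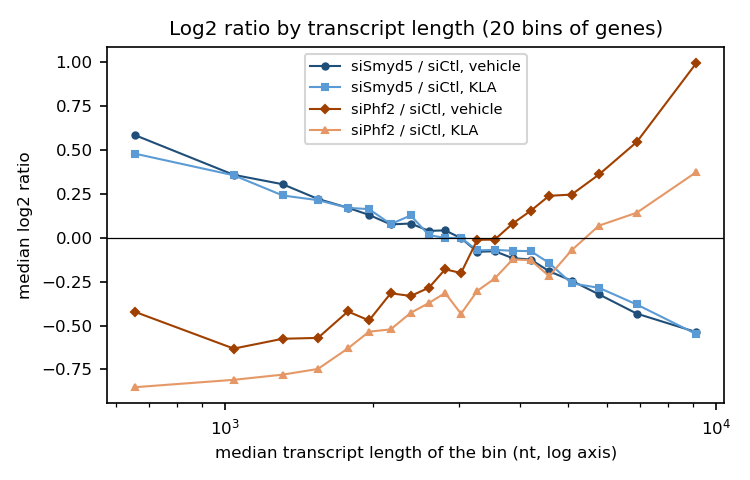
Median log2 ratio by transcript length in 20 bins for the 4 knockdown contrasts. The siSmyd5-labelled libraries ran from 0.59 (vehicle) and 0.48 (KLA) in the shortest bin to −0.54 and −0.55 in the longest, and the siPhf2-labelled libraries from −0.42 and −0.85 to 0.996 and 0.375.

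What the siSmyd5 label meant for KLA-induced genes was asked with 405 genes called induced in the siPhf2-labelled arm, whose libraries are outside the contrast. Their median log2 ratio was −0.16 under vehicle (percentile 0; 4 higher, 33 lower by size; −0.15 with genes at 0 reads at their bound) and 0.15 under KLA (percentile 100; 12 higher, 8 lower). With the length correction the medians were −0.14 and 0.08, and with the siCtl and siPhf2 names exchanged −0.69 and −0.51. The siPhf2-labelled arm is the shallowest. Of 668 genes called higher by size there, 324 were also called higher in the siCtl-labelled and 377 in the siSmyd5-labelled arm. Some of the 405 may therefore be noise of that arm.

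What differed between the siPhf2- and siCtl-labelled libraries over both agents was asked with the averaged fit, and 1000 of 7995 genes changed (646 rose, 354 fell). Because Phf2 was lower under this label only when scaled to the total, the directions are those of the labels. The largest rises included the vault RNA Vaultrc5 (log2 fold 12.50, standard error 0.41, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p 7.44e-14; 2478 and 1147 reads against at most 4 elsewhere), the ribosomal RNA precursor Rn45s (8.86) and the RNase MRP RNA Rmrp (8.53). Of the interferon-stimulated list 20 of 36 rose and 0 fell (25 and 0 adjusted over the list alone), with the nucleotide kinase Cmpk2 (3.24), Gbp5 (2.98), Rsad2 (2.64) and Mx1 (2.41) among them. Cytokines were mixed, with 4 of 25 up and 2 down (5 and 3 alone): Il1b (2.84) and Tnf (1.97) rose, while Ccl2 (−1.76) and Ccl7 (−2.98) fell. The fall of Ccl7 rested on the siPhf2 KLA library, with 1 read, and stood at 0.55 without it; Ccl7 did not pass with DESeq2. Of the LPS effectors 6 of 20 rose and 1 fell (7 and 1 alone), Irg1 (2.67) and Nos2 (2.29) among those that rose, and of the NF-kB list 4 of 22 rose and 0 fell (8 and 0 alone). The log2 folds of Tnf, Srebf2 and Apoe were −0.20, −0.84 and −0.43 when libraries were scaled to the total, and only that of Srebf2 passed there.

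Sterol synthesis genes rose under the siPhf2 label, 4 of 16 with 0 falling (6 and 0 adjusted over the list alone), the sterol regulator Srebf2 (log2 fold 1.34) among them. Of the unfolded protein and amino acid stress list 7 of 18 fell, 1 rose and 10 did not pass (9 fell and 2 rose within the list alone), with falls of the endoplasmic reticulum chaperones Pdia4 (−1.80) and Hspa5 (−0.83). In the lipid handling list 3 of 20 rose and 3 fell (5 and 3 alone), with the apolipoprotein Apoe up (1.75) and the scavenger receptor Cd36 down (−1.95). Of 6 mesothelial and fibroblast markers 0 rose and 2 fell (0 and 5 alone), the collagen Col3a1 (−2.55) and the proteoglycan Dcn (−1.86). The translation factor subunit Eif3e had 0 reads in both siPhf2-labelled libraries and 153 to 184 in the others, at least 5.28-fold lower under vehicle and at least 3.78-fold lower under KLA.

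The siPhf2 count was 487 with DESeq2, 964 with limma-voom and 543 with limma on log2 values. It was 218 without the siCtl vehicle library, 210 without siCtl KLA, 548 without siSmyd5 vehicle, 411 without siSmyd5 KLA, 956 without siPhf2 vehicle and 1449 without siPhf2 KLA. Scaling to the total gave 38 up and 7370 down, and 340 up and 1346 down with Rn45s taken out of the total.

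Whether the siPhf2-labelled differences appeared under each agent was asked with single-library contrasts. By size 867 genes were higher and 708 lower under vehicle, and 631 higher and 582 lower under KLA (791 and 410 with DESeq2's size factors). Scaling to the total, which moved the median log2 ratio from −0.098 to −1.99 and from −0.34 to −2.32, gave 44 and 6668 under vehicle and 33 and 6786 under KLA. Taking Rn45s out of the total put these medians at −0.56 and −0.76 and gave 383 and 1695, and 313 and 1343. Both agents shared 279 higher genes (68.4 expected if independent) and 199 lower genes (51.5 expected), with 22 in opposite directions (119 expected) and a Pearson correlation across genes of 0.412. The shared counts were 30 and 5975 when scaled to the total and 329 and 145 with DESeq2's size factors.

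Single inflammatory genes were higher in the siPhf2-labelled vehicle library, among them Tnf 11-fold (6.37 to 19.0), Irg1 11.3-fold (6.64 to 19.3), the chemokine Cxcl2 109-fold against 1 control read (15.9 to 4695) and Il1b at least 33.1-fold. Under KLA Il1b was 5.34-fold higher (4.67 to 6.09), Tnf 2.40-fold (2.22 to 2.6), Rsad2 8.52-fold (7.88 to 9.21) and Cmpk2 10.2-fold (8.93 to 11.5), while Ccl2 was at 0.208 of control (0.137 to 0.303) and Ccl7 at 0.0449 (0.00113 to 0.252). The cytokine medians were 0.50 under vehicle and 0.47 under KLA (percentiles 99.8 and 100; 0.62 under KLA with genes at 0 reads at their bound), with 3 of 25 higher and 3 lower under vehicle and 6 higher and 4 lower under KLA, but −1.09 and −1.79 when scaled to the total, at percentiles 100 and 99.2 there. Of the LPS effectors 4 of 20 were higher and 2 lower under vehicle, and of the NF-kB list 3 of 22 were higher and 1 lower.

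Interferon-stimulated genes split by agent under the siPhf2 label. Under vehicle 8 of 36 were higher and 6 lower (median −0.16, percentile 11.4; −0.0023 with genes at 0 reads at their bound), with the interferon regulator Irf7 at 0.0344 of control (0.00416 to 0.125) and Oas3 at 0.103 (0.0278 to 0.265). Under KLA 26 of 36 were higher and 0 lower, with a median of 1.61 (percentile 100) that was −0.65 when scaled to the total, still at percentile 100. Usp18 had 0 reads in the siPhf2-labelled vehicle library against 43 in control, at least 1.45-fold lower, and was 3.04-fold higher (1.97 to 4.54) under KLA. The difference between agents was not tested.

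Sterol synthesis genes were higher in the siPhf2-labelled libraries under vehicle, 7 of 16 with 0 lower and a median of 0.99 (percentile 99.99), and under KLA, 5 of 16 with 0 lower and a median of 0.40 (98.3; 0.79 with genes at 0 reads at their bound), but −0.96 and −1.70 when scaled to the total, at percentiles 100 and 97.7 there. The siSmyd5 contrasts used the same control libraries. Higher sterol synthesis genes, or interferon-stimulated genes under KLA, under both labels are therefore not independent observations. Srebf2 was 2.71-fold higher (1.96 to 3.71) under vehicle and 2.36-fold (1.65 to 3.30) under KLA, but at log2 ratios of −0.64 and −1.02 when scaled to the total. Unfolded protein and amino acid stress genes were lower, with medians of −0.88 (percentile 0; 0 of 18 higher, 7 lower) and −0.90 (0.570; 1 higher, 5 lower; −0.69 with genes at 0 reads at their bound), and Pdia4 was at 0.156 of control (0.0421 to 0.403) and 0.481 (0.206 to 0.962). With the length correction the medians of that list were −0.36 (percentile 2.10) and −0.32 (4.10), the latter inside the central 95% of random lists. Of 24 small and ribosomal RNA genes 19 were higher and 0 lower under each agent, with medians of 6.62 and 6.08. Under the siSmyd5 label 5 of these 24 were higher and 0 lower under each agent, with medians of 0.59 and 0.37. There 35 (vehicle) and 24 (KLA) of 319 non-coding transcripts were higher and 1 and 3 lower. Of 7676 coding transcripts 157 and 114 were higher and 400 and 288 lower. These counts were not corrected for length, and short transcripts ran higher under the siSmyd5 label.

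**Figure D4:**
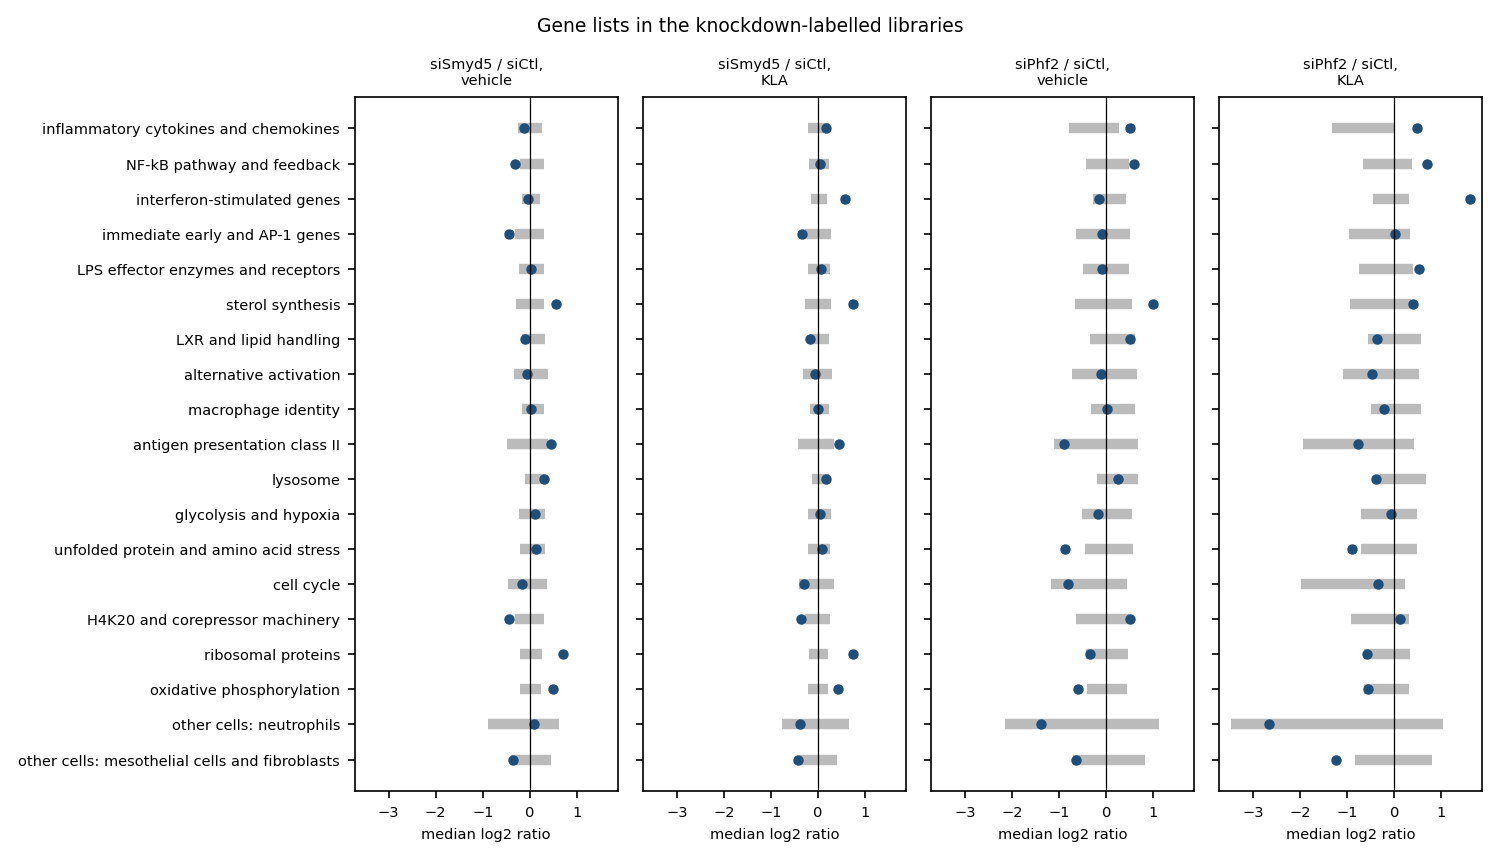
Median log2 ratio of each gene list in the 4 knockdown contrasts, with the central 95% of random matched lists in grey. Sterol synthesis stood at 0.55 and 0.74 under the siSmyd5 label and 0.99 and 0.40 under the siPhf2 label. Within an agent both labels were set against the same siCtl-labelled library, so a like shift under both is not an independent observation.

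What the siPhf2 label meant for KLA-induced genes was asked with 252 genes called induced in the siSmyd5-labelled arm. Their median log2 ratio was 0.37 under vehicle (percentile 100; 52 higher, 9 lower by size; 0.64 with genes at 0 reads at their bound) and 0.71 under KLA (percentile 100; 91 higher, 10 lower; 0.73 at the bound), but −1.25 and −1.51 when scaled to the total, both still at percentile 100. With genes induced at a log2 ratio of at least 1 the medians were 0.05 (percentile 99.45) and 0.47 (100). Without a filter they were 0.0 (percentile 99.955) and 0.34 (100).

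Whether the siSmyd5- and siPhf2-labelled libraries differed from control in the same genes was asked with correlations across genes. The Pearson correlations were −0.12 under vehicle and −0.07 under KLA, where simulations of unchanged groups sharing a control gave 0.157 and 0.117. Across agents, with no library shared, they were −0.16 and −0.17. After the length correction those within an agent were 0.02 and 0.04. Rpl13 and the microRNA gene Mir5109 were the only genes higher in all 4 knockdown contrasts.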

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

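The tests of mesothelial cells or fibroblasts, of exchanged names and of carry-over were chosen only after the result was seen, as were the other scalings of the histone reads. The tests of length and poly(A) selection were written before their values, though the ribosomal protein test was split by agent after its values were seen, with the same bounds, and the histone test was changed from a list median to summed reads before its values were seen.

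The siSmyd5 label went with opposite differences under the 2 agents: the median log2 ratio of KLA-induced genes, taken from the shallow siPhf2-labelled arm, was −0.16 under vehicle and 0.15 under KLA, but −0.69 and −0.51 with the siCtl and siPhf2 names exchanged, which loses the opposite signs. The siPhf2 label did the same for Usp18, with log2 ratios of −3.67 (2 reads added) under vehicle and 1.58 under KLA. With 0 reads against 43 the vehicle value is only a bound of at least 1.45-fold lower, and the KLA value was −0.66 when scaled to the total, so that these signs were opposite only under the other scalings. A difference between the agents drew attention in each case and was not tested.

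In the siSmyd5-labelled libraries short transcripts were higher and long ones lower, and in the siPhf2-labelled libraries the reverse. After the length correction the ribosomal protein median was at percentile 77.95 of random lists under vehicle, in line with a length bias, but stayed at 99.8 under KLA, above what length alone left. Of the 113 genes lower under both agents 47 stayed at least 2-fold lower, which leaves open how far length accounts for them. Of 6 measured markers of mesothelial cells and fibroblasts 5 lay above the median of those genes under both agents, with Pdgfra the exception. The 6 were Col1a1, Col1a2, Col3a1, Dcn, Pdgfra and Sparc, so the mesothelial members Msln and Upk3b were not covered. The genes lower under both agents were picked for being lower, so markers above their median do not decide against fewer fibroblasts. A loss of mesothelial cells was not tested. The marker medians were themselves −0.36 (percentile 3.92) and −0.42 (1.39), so a loss of such cells stays open. An effect of the siRNA stays open and was not tested, and the labels do not give fragment sizes by library.

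Phf2 was higher in the siPhf2-labelled vehicle library at 2.54-fold and stood at 1.08 under KLA (0.595 and 0.223 when scaled to the total), and small and ribosomal RNAs were much higher under both agents. Histone genes, whose mRNAs mostly lack poly(A) tails, were higher as well, with summed reads at 2.44 of control (1.32 to 4.27; 16 reads against 65) under vehicle and 3.46 (1.56 to 6.93; 10 against 47) under KLA, but at 0.571 and 0.713 when scaled to the total, which Rn45s fills and which put the median log2 ratio of all genes at −1.99 and −2.32, so that this scaling decides nothing here. With Rn45s taken out of the total they stood at 1.73 (0.937 to 3.03) and 2.53 (1.14 to 5.08), under vehicle not beyond counting error in a scaling that still put the median of all genes at −0.56, so weaker poly(A) selection stays undecided. An exchange of the siCtl and siPhf2 names would predict a higher Phf2 under both agents, which was seen under vehicle but not beyond counting error under KLA (0.457 to 2.20; 8 reads against 120), so the exchange stays undecided. An effect of the siRNA stays open and was not tested.

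In the siPhf2-labelled vehicle library 41 strongly KLA-induced genes held 325 reads against 106 at the level of the other vehicle libraries, unevenly: Irg1 held 33 and Tnf 31, while Ccl2 (9 against 10.5) and Ptgs2 (6 against 9.67) lay below that level. A carry-over of 1.87% (1.61 to 2.16) of the siPhf2 KLA library, 5.42% of siCtl KLA or 4.86% of siSmyd5 KLA would give that sum. The 41 genes were picked for a strong rise in the siCtl- and siSmyd5-labelled arms, whose vehicle libraries also set the 106. Part of the excess and of these shares may come from that choice. With counting error only, the spread over genes argued against each source (simulation p 0.0025, 0.0005 and 0.0005, in that order). A wider spread, taken from 3241 non-responding genes and added after those p-values were seen, gave 0.9625, 0.9805 and 0.991, so carry-over stays undecided. An effect of the siRNA on inflammatory genes stays open and was not tested.

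Splitting the 6 libraries 3 against 3 gave 1256 genes for vehicle against KLA, and 0 at most in any other split. Thus 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The other splits mixed vehicle and KLA libraries on both sides, so the KLA effect entered their residual and few calls could arise. Some of them also kept both libraries of an arm on the same side. The splits therefore decide nothing here.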

How the results depend on the processing

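The exchange of the siCtl and siPhf2 names, fits without an siRNA's libraries or without Rn45s, total scaling without Rn45s and the length correction were tests chosen only after the results were seen. Of 162 values for the comparisons 96 stayed, 58 moved and 8 reversed; of 373 list medians 319 stayed, 37 weakened and 17 reversed. Of 1245 values for genes named from the averaged fits 1018 stayed, 2 strengthened, 219 weakened and 6 reversed, and of 393 for genes named from single libraries 320 stayed, 59 moved and 14 reversed. For averaged effects these words describe passing the threshold, and a sign change counted as reversed only if the main value had passed. Phf2 under the siPhf2 label thus counted as strengthened, from 0.90 to −1.26 with total scaling. Smyd5 under the siSmyd5 label counted as stayed, from −0.64 to 0.23 without the siSmyd5 vehicle library. The siPhf2 values under the exchange of names were left out. Where no cause is given below, the cause was not tested.

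With DESeq2 the averaged counts were 613 (KLA), 14 (siSmyd5) and 487 (siPhf2), with limma on log2 values 375, 0 and 543, and with no block for the other factor 234, 0 and 25, while limma-voom gave 16 for siSmyd5. Leaving out 1 library gave 416 to 2050 genes for KLA, 1 to 2196 for siSmyd5 and 210 to 1449 for siPhf2, and leaving out an arm 483 to 2110 for KLA. In those fits a lone library is assumed to vary like the other groups. The siSmyd5 count was 2194 without the siPhf2 libraries and the siPhf2 count 586 without the siSmyd5 libraries. Ccl7 in the averaged siPhf2 effect ran from −4.50 without the siPhf2 vehicle library to 0.55 without the siPhf2 KLA library.

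Total scaling gave 232 genes for siSmyd5 and 7408 for siPhf2, with 6712 genes called for siPhf2 under vehicle, 6819 under KLA and 6005 under both; Rn45s took most siPhf2-labelled reads, and without it the totals gave 1686 for the averaged effect and 786 under both agents. KLA-induced genes then had siPhf2 medians of −1.25 under vehicle (−0.064 without Rn45s) and −1.51 under KLA. Under vehicle the siPhf2 medians of the cytokine, NF-kB, sterol synthesis and H4K20 lists were −1.09, −1.30, −0.96 and −1.48. Under KLA those of the cytokine, NF-kB, interferon-stimulated, LPS effector and sterol synthesis lists were −1.79, −1.55, −0.65, −1.74 and −1.70, the last −0.033 without Rn45s. The averaged siPhf2 effects of Apoe, Srebf2 and Tnf were −0.43, −0.84 and −0.20. Under KLA the siPhf2 log2 ratios of Srebf2, Tnf and Usp18 were −1.02, −1.01 and −0.66, and those of Srebf2 and Phf2 under vehicle −0.64 and −0.72. This scaling shifts the siPhf2 ratios down as a whole. Of these 9 list medians 7 changed sign but stayed above the central 95% of random lists, while the H4K20 list under vehicle (percentile 98.12 before, 97.3 after) and the LPS effector list under KLA (99.11 before, 96.4 after) fell inside it.

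With a minimum mean of 50 reads, which tests fewer genes, 346 genes were called for KLA in the siCtl-labelled and 436 in the siSmyd5-labelled arm, 190 for siSmyd5 under vehicle, 106 under KLA, 51 under both, and 905 for siPhf2 under vehicle. The correlations of the siSmyd5 and siPhf2 contrasts were then −0.25 (vehicle) and −0.18 (KLA). With 5 times the added reads 636 genes were called for KLA in the siSmyd5-labelled arm and 207, 140 and 48 for siSmyd5 under vehicle, KLA and both. Without a filter 658 genes were called for siSmyd5 under KLA, the ribosomal protein median for KLA in the siCtl-labelled arm was 0.026, and the mesothelial and fibroblast median for siSmyd5 under KLA was 0.046.

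With the siCtl and siPhf2 names exchanged the siSmyd5 counts were 2021 averaged, 2280 under vehicle, 1679 under KLA and 935 under both, and KLA-induced genes under KLA had a median of −0.51. The siSmyd5 medians became −0.28 for sterol synthesis under vehicle, and under KLA −0.96 for interferon-stimulated genes, 0.39 for lipid handling and 0.83 for mesothelial and fibroblast markers. The correlations of the siSmyd5 and siPhf2 contrasts became 0.93 and 0.95, beside a simulated 0.915 and 0.956 for unchanged groups sharing a shallow control. The covariances of these contrasts were 1.782 and 2.509, above the simulated 0.4505 and 0.9718. Across agents, with no library shared, the correlations were still 0.424 and 0.436. Counting error in the shared control therefore does not account for all of the likeness. Dusp4 and Myc stood at 1.11 and 1.21 in the averaged siSmyd5 effect, Ctgf, Cyp51, Dusp4 and Myc at 1.58, −0.020, 1.03 and 0.32 under vehicle, and Ctgf, Ifi47, Mx1, Mx2 and Usp18 at 0.20, −0.83, −1.57, −1.22 and −0.42 under KLA. The siPhf2 contrasts only change sign under the exchange and the averaged KLA effect is unaffected.

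The length correction left 262 genes called for siSmyd5 under KLA and 81 under both agents, turned the correlations of the siSmyd5 and siPhf2 contrasts to 0.018 and 0.037, and put the siPhf2 lysosome median under KLA at 0.21. Across agents the correlation of siSmyd5 under KLA with siPhf2 under vehicle was −0.17. Depth limited the siPhf2-labelled libraries most: the averaged fit recovered 59.5% of simulated 4-fold changes there against 95.5% for siSmyd5.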

Other observations

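Apart from the counts adjusted over a list alone, which the plan did not name, none of the values here came from tests chosen only after the result was seen. The metabolic and cell-state lists in the averaged KLA fit are counted here, beside 891 of 7995 genes that rose and 365 that fell over all genes. Of the glycolysis and hypoxia list 2 of 16 rose and 0 fell (2 and 0 adjusted over the list alone), the hexokinase Hk2 (log2 fold 1.36) and Hif1a, and of the cell cycle list 2 of 11 rose and 0 fell (2 and 0 alone), the proliferation marker Mki67 (3.08) and Ccne1. Of the unfolded protein and amino acid stress list 3 of 18 rose and 0 fell (3 and 0 alone), of the class II list 1 of 8 rose and 0 fell (2 and 0 alone) and of the alternative activation list 1 of 10 rose and 0 fell (0 and 0 alone). Of sterol synthesis genes 1 of 16 rose, Insig1 (1 and 0 alone), of lysosomal genes 0 of 22 rose and 1 fell, Ctsd (0 and 1 alone), of ribosomal protein genes 0 of 27 changed, and of oxidative phosphorylation genes 0 of 27 rose and 1 fell, Ndufs3 (0 and 0 alone).

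Under the siSmyd5 label 0 of 22 lysosomal, 0 of 18 stress, 0 of 8 class II and 0 of 11 cell cycle genes passed (1 cell cycle gene up within its list alone), while 1 of 16 glycolysis and hypoxia genes rose (2 within the list alone) and 1 of 10 alternative activation genes fell (1 alone). Under the siPhf2 label 2 of 22 lysosomal genes rose and 4 fell (3 and 4 alone), 3 of 21 macrophage identity genes rose and 3 fell (3 and 4 alone), 3 of 17 immediate early genes rose and 2 fell (4 and 2 alone), and 2 of 16 glycolysis and hypoxia genes rose and 1 fell (2 and 2 alone). Of 10 alternative activation genes 1 rose and 2 fell (3 and 2 alone), of 27 oxidative phosphorylation genes 0 rose and 3 fell (0 and 3 alone), of 27 ribosomal protein genes 1 rose and 1 fell (1 and 1 alone), of 8 class II genes 0 rose and 1 fell (0 and 1 alone) and of 11 cell cycle genes 0 rose and 1 fell (0 and 1 alone). In the H4K20 and corepressor list 2 of 17 rose, Kdm4a among them, and 0 fell (3 and 0 alone).

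Most listed markers of other cells lay below the read filter, while 6 of 13 mesothelial and fibroblast markers lay above it. The 3 neutrophil genes above the filter showed 0 changes with KLA, 1 rise under the siSmyd5 label (S100a8) and 1 fall under the siPhf2 label (Mmp8). The only T and NK cell gene above the filter, Il7r, did not pass in any fit over all genes. Its log2 folds of −0.45 with KLA and 0.54 under the siSmyd5 label reached an unadjusted edgeR quasi-likelihood p under 0.05. So did 2124 and 1886 of 7995 genes in those fits, and a list of 1 gene allows no adjustment. Of 6 mesothelial and fibroblast markers 0 changed with KLA and 1 fell under the siSmyd5 label, the growth factor receptor Pdgfra (log2 fold −1.09).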
